A study of Homo sapiens with 2 samples.

How the data were processed

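HCT116, a cell line derived from a human colorectal carcinoma, was transiently transfected with a precursor of miR-147 or with a non-coding miR as negative control, per the labels. The labels' protocols state that 5 independent transfections were made of each kind and that their RNA was pooled in equal amounts before analysis. Each pool was hybridised to 1 Affymetrix U133 Plus 2.0 array, so each group holds 1 array. Total RNA was amplified and labelled with biotin using the Ambion Message Amp Premier kit, per the labels' protocols.

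The deposited signal intensities were made with MAS5 in GCOS 1.4, per the submitters' processing notes. MAS5 gives each probe set a linear intensity from its matched and mismatched probes and a detection call of Present, Marginal or Absent. The deposited values cover all 54675 probe sets of both arrays, and their 2% trimmed means were 500.07 on the miR-147 array and 500.066 on the control array, which shows that both arrays had been scaled to a common level. A further table deposited by the authors covers 9173 of these probe sets, and each of its rows carries a MAS5 call of increase (4148) or decrease (5025). That table also holds gene names, detection calls, a change p-value made by the authors' comparison software, and a signed fold deposited by the authors. Its change p-values reached at most 0.001832 for increases and at least 0.998124 for decreases. They compare the probes of these 2 arrays and say nothing about the spread between cultures, so they were not used as tests. The deposited fold differed from the ratio of the deposited signals by at most 0.005, and the signals of both tables differed by at most 0.1. For 57 probe sets the ratio of the signals went against the change call.

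Genes could be named only inside the change table, which the authors had selected for differences. Every statement on a named gene or gene list is therefore a statement within that selection, and a gene without a row there was not analysed here. Of the 9173 probe sets, 8069 carried 1 named gene, 363 several genes, 14 were controls and 727 had no single gene name. Only those with 1 name were used for genes. The gene identifiers of 7889 were found in the RefSeq gene table of GRCh38.p14, which updated 878 symbols, and 180 kept the symbol of the file. In 8 probe sets the symbol had been turned into a date by spreadsheet software. The authors' annotation puts a caution comment on 143 probe sets. The files name no genome build, so no coordinates are given. A few list members and 1 set of control probe sets are not reported here.

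The value of a gene was the log2 ratio of the deposited intensity on the miR-147 array over that on the control array, as scaled by the authors, with no pseudocount. Among probe sets called Present on both arrays, the one with the highest mean log2 signal stood for its gene, which gave 5407 detected genes out of 5736 named ones. Of these genes, 1553 had at least 2 detected probe sets, and in 105 of them (6.76%) the probe sets disagreed in sign. The SD between detected probe sets of a gene was 0.39 on the log2 scale. It is the error estimate used for a gene here. This SD and the share of disagreeing signs rest on probe sets with a change call, which leaves out unchanged probe sets of the same genes. Error shared by all probe sets of an array and the spread between transfections are not in the SD. The number of arrays limits the precision.

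No test was possible with 1 array per group, and no p-value across genes was computed. Sizes are given in its place: the number of genes at least 2-fold higher or lower, and for each gene list the number at least 1.5-fold higher or lower and the median log2 ratio. The median of a list with at least 5 detected genes was ranked among 10000 random lists of the same size, drawn from the detected genes and matched on mean expression in 20 bins. A list was said to stand apart when its percentile was under 1 or over 99, which describes these arrays only. For a gene called Absent on 1 array by every probe set it has in the change table, the ratio was given as a bound against the higher of the Absent probe set's own signal and the floor of that array, the 5th percentile of signals called Present there in the change table.

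Before the data were examined, the gene lists, the rule for named genes and most alternatives were fixed. Named were the 15 genes with the highest and the 15 with the lowest ratio among detected genes at or above the 25th percentile of mean signal whose probe sets shared a sign, the 5 largest bounds each way, up to 3 list members each way, and a few genes fixed by name. The alternatives were the median of detected genes set to 0, quantile normalization, a pseudocount of 32, other detection filters, other ways to choose a probe set, removal of a lowess trend of the ratio on mean signal, other fold thresholds and 5 expression bins. Scaling on the hybridisation spike-ins, scaling on the whole-array median, leaving out probe sets with a caution comment, the counts over the whole array and the scan of gene ontology terms were chosen after seeing the data.

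The comparison of genes with and without a miR-147 seed match in the 3' UTR, planned beforehand, was not run, because no transcript sequences were used here. The procedure was tested on simulated data with the 5407 genes. Changes of 1.5 on the log2 scale were recovered as at least 2-fold in 90% of cases and changes of 2.5 in 100%, while 0.807% of unchanged genes passed the 2-fold threshold. Of 100 simulated lists without a shift, 1% fell outside percentiles 1 to 99, and 98% of lists shifted by 0.5 lay above percentile 99. All of these shares hold for the simulated data only. The 0.807% does not estimate how many unchanged genes pass the threshold on the real arrays. There, 16123 probe sets outside the change table, other than controls, had both signals at or above the array medians. Of these, 393 were at least 2-fold higher and 198 at least 2-fold lower. In the real data the SD of random list medians ran from 0.024 for ribosomal proteins to 0.62 for NF-kB targets. For the 18 integrin and focal adhesion genes, random lists had a median of -0.30 and their percentile 99 lay at 0.61. A list shifted up by 0.5 from that median would not stand apart there. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.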

Results

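Gene expression was measured in HCT116 cells, a human colorectal carcinoma line, after transfection with precursor miR-147 or with a control miR. The comparison asks which transcripts differ when this microRNA, a short RNA that lowers the output of the messenger RNAs it pairs with, is supplied to the cells. Each group consisted of 1 array, hybridised with RNA pooled from 5 transfections, so no difference below has a replicate check and only sizes are given. Values are log2 ratios of the signal on the miR-147 array over that on the control array. The error estimate used for a gene is the SD of 0.39 between change-called probe sets of the same gene. Median signals over all 54675 probe sets were 72.4 on the miR-147 array and 60.8 on the control array. In the 9173 probe sets to which the authors' deposited table gives a change call, 8680 were called Present on the miR-147 array and 8865 on the control array.

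Transcripts of p53 target genes were higher with miR-147, while transcripts for DNA replication and mitosis were lower. Among the 5407 named genes detected on both arrays, 576 were at least 2-fold higher and 766 at least 2-fold lower. Of the genes past this threshold, 42.9% were thus higher. This split depends on the scaling: with the median of the detected genes set to 0, a shift of 0.26, it was 1119 higher and 427 lower (72.4% higher), and with the hybridisation spike-ins set to 0, a shift of -0.35, it was 219 higher and 1533 lower (12.5% higher). These genes come from a table already selected for change calls. Over the whole array, without names, 24963 probe sets other than controls had both signals at or above the array medians. Of these, 1427 were at least 2-fold higher and 1574 at least 2-fold lower.

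**Figure D1:**
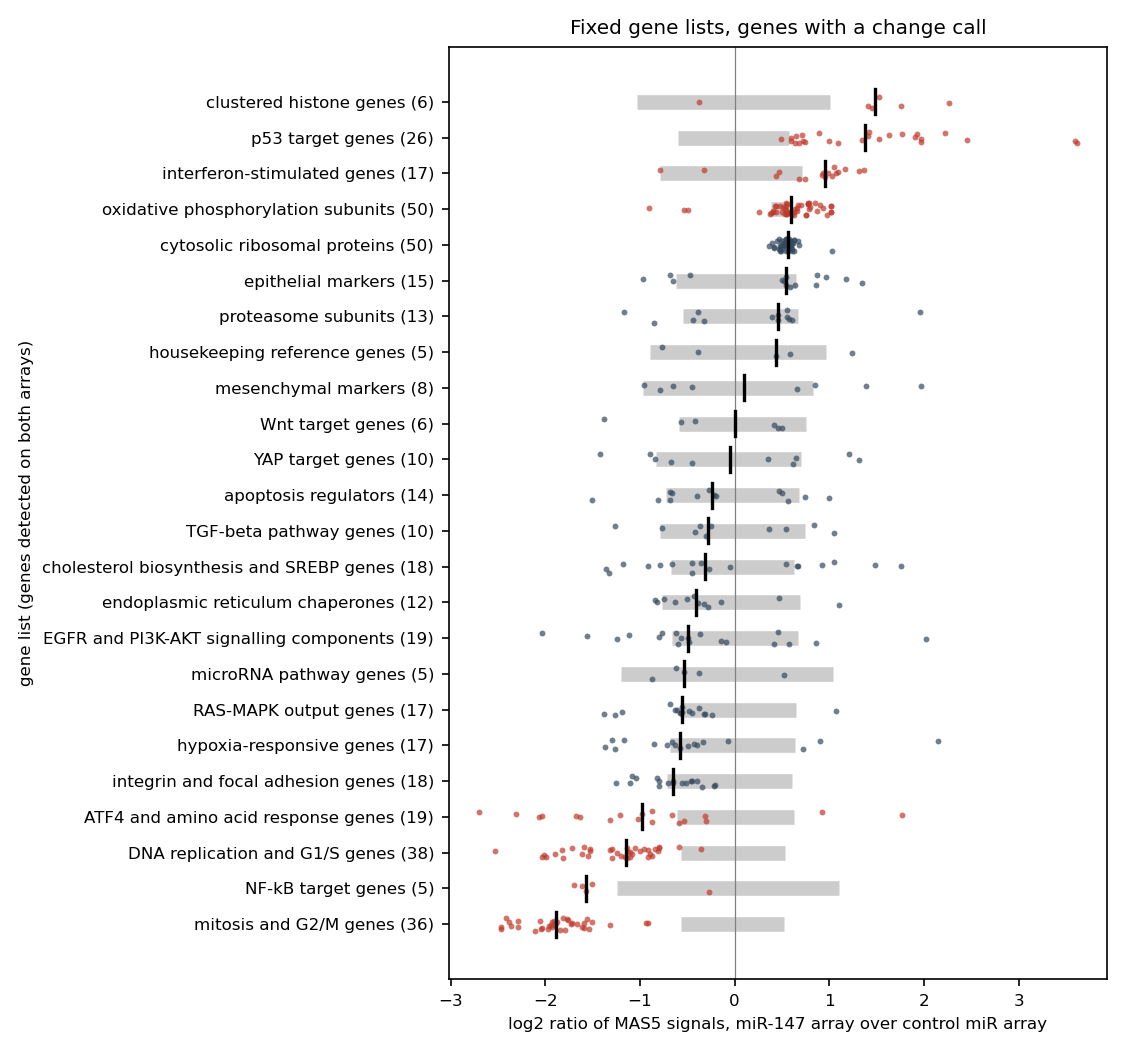
Log2 ratio of the signals (horizontal axis, miR-147 array over control array) for the detected genes of each fixed gene list (vertical axis, with the number of genes in parentheses). Points are genes, black bars are list medians, grey bars span percentiles 1 to 99 of the medians of random lists matched on expression, and red marks lists outside that span. The mitosis list has the lowest median (-1.88), and the p53 and histone lists have the highest (1.37 and 1.49). Under the scaling alternatives the medians of the red lists keep their sign, while those of the mesenchymal, Wnt, YAP, apoptosis and housekeeping lists change sign under at least 1 of the alternatives.

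Of the 26 detected targets of p53, a transcription factor activated by DNA damage and other stress, 25 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. Their median log2 ratio was 1.37 (2.59-fold), above all 10000 random lists of matched expression, whose median was -0.25. TP53I3 (gene ID 9540), an oxidoreductase induced by p53, had signals of 8265 with miR-147 and 684 in the control, a log2 ratio of 3.60. The log2 ratio of TRIM22 was 3.62, from a dim control signal of 57.1. FDXR, the mitochondrial ferredoxin reductase, had signals of 8031 and 1464 (2.46), and the 4 detected probe sets of the zinc finger gene ZMAT3 gave 2.02 to 2.40, with a caution comment on the probe set that stood for the gene. CDKN1A (gene ID 1026), which encodes the cyclin-dependent kinase inhibitor p21, had signals of 16673 with miR-147 and 5791 in the control (1.53). The smallest ratios of the list were 0.49 for the death receptor gene TNFRSF10B and 0.60 each for RRM2B and MDM2, the last of which encodes the ubiquitin ligase that targets p53.

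The 36 detected mitosis and G2/M genes were all at least 1.5-fold lower with miR-147. Their median log2 ratio was -1.88, a 3.69-fold lower signal, below all random lists, and all 36 stayed below 0 in each scaling alternative. MKI67 (gene ID 4288), the proliferation marker Ki-67, had signals of 628 with miR-147 and 3486 in the control (-2.47), and its 4 probe sets ranged from -2.76 to -2.14. The kinetochore genes CENPF and CENPE had log2 ratios of -2.47 and -2.41, and KIF11, the kinesin that separates spindle poles, had -2.38. The smallest differences were those of CKS2 (-0.92), MAD2L1 (-0.94) and the phosphatase gene CDC25B (-1.31).

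Of 38 detected DNA replication and G1/S genes, 37 were at least 1.5-fold lower, with a median of -1.14 (2.21-fold lower) that lay below all random lists. GINS2, a subunit of the replicative helicase complex, had a log2 ratio of -2.04, and ORC1, a subunit of the origin recognition complex, had -2.02. SLBP, the histone mRNA binding protein, was nearest to 0 at -0.36. Of the genes fixed by name, CCND1, which encodes cyclin D1, had a ratio of -1.38, with signals of 2672 and 6957.

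Of 8 genes that earlier work names as miR-147 targets, 3 had a detected row among the change calls. Their ratios come from that selection and do not describe the 8 as a group. The helicase subunit MCM3 had signals of 1987 with miR-147 and 7029 in the control (-1.82). It is also a member of the replication list, whose 38 detected genes all lay below 0. The kinase gene AKT2 had -1.55, from 1 of its 5 probe sets on the array and with a caution comment in the annotation, and the growth factor gene VEGFA had -0.63, from 1 of 4. NDUFA4, SDHD, PSMA3 and ZYG11B were not analysed here.

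Genes of the amino acid response driven by the transcription factor ATF4 were lower. Of 19 detected, 14 were at least 1.5-fold lower and 2 higher, with a median of -0.98 that lay below all random lists. The pseudokinase gene TRIB3 had signals of 962 and 6263 (-2.70), PHGDH, the first enzyme of serine synthesis, had -2.30, and CHAC1, which degrades glutathione, had -2.06. The exceptions were CTH, the cystathionine gamma-lyase, at 1.76, and ATF3 at 0.92.

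Only 5 of the 24 NF-kB target genes were detected among the change calls, and the rest of the list did not enter these values. Those 5 were all lower. Of these, 4 were at least 1.5-fold lower, and the median of -1.57 lay at percentile 0.185 of random lists. CXCL1 (-1.70) and CXCL8 (-1.57) encode chemokines that attract neutrophils, and NFKBIA (-1.61) encodes the inhibitor that NF-kB induces. The apoptosis inhibitor gene BIRC3 had signals of 234 and 663, and NFKB1 had -0.27. Control signals of the chemokines were low, at 385 for CXCL1 and 399 for CXCL8. Their signals with miR-147, 118 and 134, lay below the Present floor of 144 on that array, which limits both ratios.

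Interferon-stimulated genes were higher as a group. Of 17 detected, 13 were at least 1.5-fold higher and 1 at least 1.5-fold lower, with a median of 0.95 (1.94-fold) at percentile 99.97. PARP9 had a ratio of 1.37, the ubiquitin-like modifier ISG15 had signals of 7646 and 3077 (1.31), and IFIT3 had 1.17. CMPK2 (-0.78) and IFIT5 (-0.32) lay below 0. The other genes of this list of 36 were not analysed here.

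Of 6 detected histone genes, 5 were at least 1.5-fold higher, with a median of 1.49 (2.80-fold) above all random lists. H2AC6 had 2.27, H2BC5 1.75 and H3C10 1.52.

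Subunits of the oxidative phosphorylation complexes and cytosolic ribosomal proteins, both bright on the arrays, were higher as deposited, by amounts that depended on the scaling. Of 50 detected oxidative phosphorylation subunits, 25 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. Their median was 0.59 (1.51-fold), at percentile 99.94 of random lists whose median was 0.48. NDUFA6 and NDUFA2, subunits of complex I, both had 1.02, and NDUFA7 had -0.90. All 50 detected ribosomal protein genes lay above 0 as deposited, with a median of 0.56 that did not stand apart (percentile 92.28, random median 0.53). The medians of the oxidative phosphorylation and ribosomal protein lists were 0.43 and 0.05 after quantile normalization, 0.38 and 0.15 after removal of the brightness trend, and 0.24 and 0.21 with the spike-ins set to 0. After quantile normalization 14 of the 50 ribosomal protein genes lay below 0, RPLP2, RPL15 and RPL28 among them, and after removal of the brightness trend 2 did. When the detected genes were ranked by brightness into 4 equal groups, the median was 0.40 in the brightest and -0.23, -0.37 and -0.32 in the others, from dim to bright. The same ranking, without selection on change calls, was made over the 24963 non-control probe sets at or above the median signal on both arrays. There the medians from dim to bright were 0.20, 0.02, -0.02 and 0.08. Groups this wide hide the brightest signals. The lowess trend over the same probe sets was 0.03 at a signal of 4096, 0.14 at 8192, 0.29 at 16384 and 0.44 at 32768. The hybridisation spike-ins, which carry no RNA of the transfected cells, had a median of 0.35 over 18 probe sets.

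**Figure D2:**
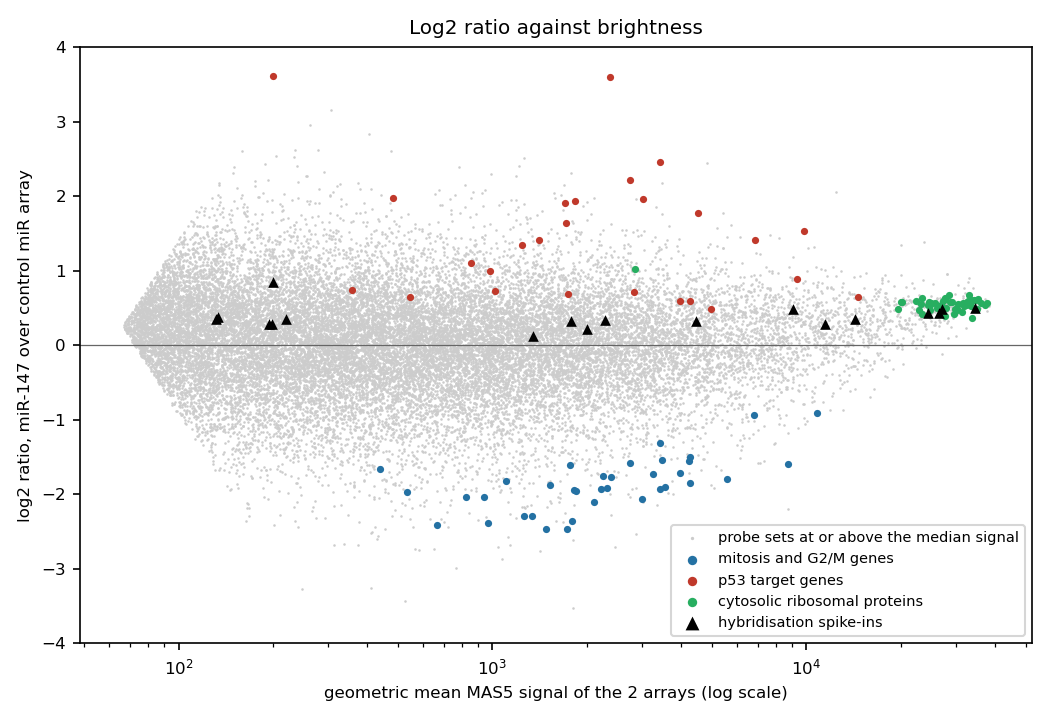
Log2 ratio (vertical axis, miR-147 array over control array) against the geometric mean signal of both arrays (horizontal axis, log scale) for probe sets at or above the median signal on both arrays (grey), with detected p53 targets, mitosis genes and ribosomal protein genes as coloured points and the hybridisation spike-ins as triangles. All 36 mitosis genes lie below 0, all 26 p53 targets above 0, and the ribosomal protein genes beside the brightest spike-ins, where as deposited all 50 lie above 0 but after quantile normalization 14 lie below 0.

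The growth factor signalling lists did not stand apart by the percentile rule, though most of their detected genes lay below 0. Of 17 detected RAS-MAPK output genes, 16 lay below 0, 6 were at least 1.5-fold lower and 1 higher. Their median was -0.55, at percentile 1.4 of random lists whose median was 0.38. The feedback inhibitor SPRY4 had -1.26, the AP-1 subunit FOSL1 -1.19 and SPRY1 1.07. Of 19 detected EGFR and PI3K-AKT components, 8 were at least 1.5-fold lower and 2 higher (median -0.50, percentile 9.625). EGFR had -0.62 from 1 of its 8 probe sets, its relative ERBB3 had 0.86, and the kinase gene PIK3CA had -1.24. BRAF (-2.04) rested on a dim probe set with a caution comment, and with a pseudocount of 32 its ratio shrank to -1.47.

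Epithelial and mesenchymal markers did not stand apart. Of 15 detected epithelial markers, 6 were at least 1.5-fold higher and 3 lower (median 0.54, percentile 89.175). CDH1, which encodes E-cadherin, had signals of 6689 and 4602 (0.54) on 1 of its 2 probe sets. KRT8, a keratin of simple epithelia, had 0.96, CLDN3 1.18 and the adaptor subunit gene AP1M2 1.35, whereas MAL2 had -0.97. Of 8 mesenchymal markers, 4 were at least 1.5-fold higher and 3 lower, with a median of 0.10 that turned to -0.25 with the spike-ins set to 0 and was 0.85 (percentile 94.035) with shared-probe suffixes left out. ACTA2 (1.97), also a member of the p53 list, and COL5A2 (1.39) were highest, and TWIST1 (-0.96) and S100A4 (-0.79) lowest. VIM, ZEB1 and ZEB2 were not analysed here.

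The remaining lists also lay between percentiles 1 and 99. Integrin and focal adhesion genes had a median of -0.65 (percentile 2.35), with 10 of 18 at least 1.5-fold lower and 0 higher. Among them the tropomyosin TPM4 had -1.25 and the urokinase gene PLAU -1.11. Hypoxia-responsive genes had a median of -0.58 (percentile 5.18), with ENO2 at -1.37 and the glucose transporter SLC2A3 at 2.15. Cholesterol and SREBP genes split evenly, 6 of 18 each way, with the fatty acid elongase gene ELOVL6 at -1.32 and TM7SF2 at 1.76. Medians were -0.41 for 12 endoplasmic reticulum chaperones, -0.28 for 10 TGF-beta pathway genes, -0.53 for 5 microRNA pathway genes and 0.46 for 13 proteasome subunits. The 5 housekeeping genes had 0.43, which quantile normalization turned to -0.06. The medians of 14 apoptosis regulators (-0.24), 10 YAP targets (-0.05) and 6 Wnt targets (-0.00035) changed sign with the median of detected genes set to 0. Of 26 intestinal differentiation genes, KLF4 (-1.63) and KLF5 (-0.73) were detected. Of 20 markers of fibroblasts, endothelium and leukocytes, 0 had a row among the change calls.

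Among detected genes at or above the 25th percentile of mean signal whose probe sets shared a sign, which leaves out the dimmer TRIM22, the 15 highest had log2 ratios from 1.94 to 3.60, and 4 of them belong to the p53 list. Besides those named above they held the mitochondrially encoded MT-ND5 (2.45) and MT-ND6 (2.06), each from 1 probe set, the dehydrogenase gene BDH2 (2.30), STAT3 (1.96, its 3 detected probe sets from 1.396 to 2.39) and TP53INP1 (1.96). The 15 lowest ran from -2.99 to -2.37, and 5 of them belong to the replication or mitosis lists. Outside those lists lay LOC100131262 (-2.99), CALML4 (-2.87), DHRS2 (-2.75), the condensin subunit NCAPH (-2.74), CIP2A (-2.73), GPAT3 (-2.71), the membrane protein gene EMP1 (-2.69) and REEP3 (-2.62). The 4 probe sets of CALML4 ranged from -3.26 to -0.63, and their mean over the gene was -2.13.

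**Figure D3:**
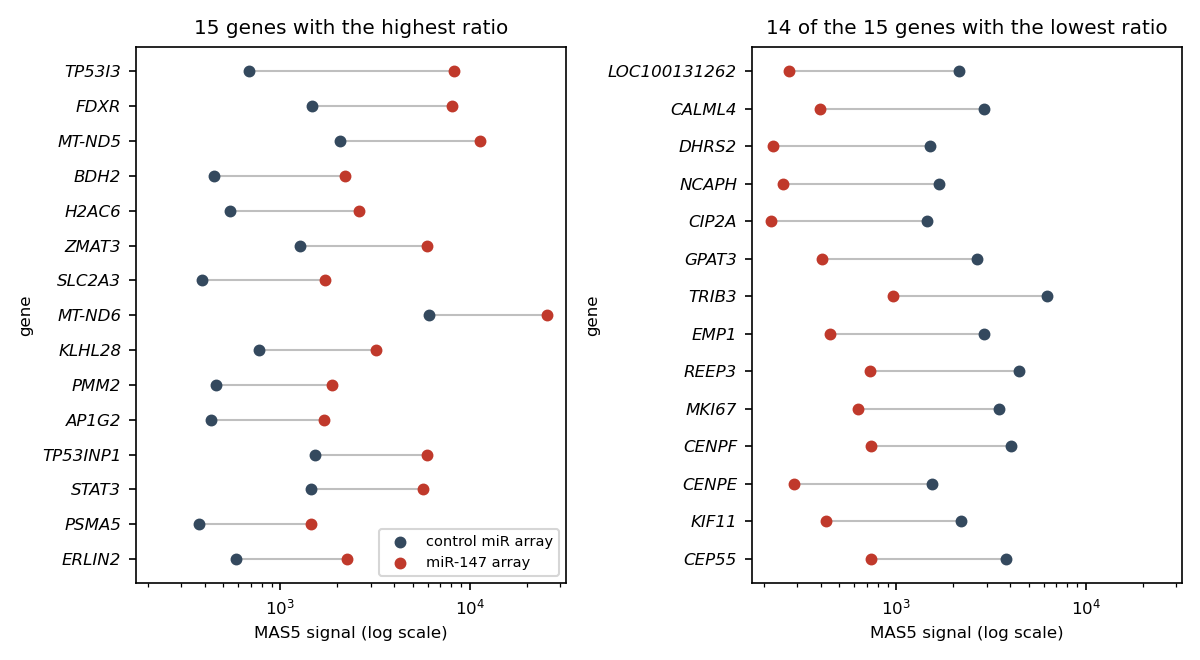
Signal (horizontal axis, log scale) of the 15 genes with the highest ratio (left panel) and of 14 of the 15 with the lowest (right panel), 1 row per gene on the vertical axis, among detected genes at or above the 25th percentile of mean signal whose probe sets share a sign. Red points are the miR-147 array and dark points the control array, 1 array each with no error bar, and TP53I3 runs from 684 in the control to 8265 with miR-147.

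For genes called Absent on 1 array by every probe set they have in the change table, the ratio is a bound, and only bounds above 1-fold were kept. Other probe sets of these genes on the array have no detection call. Of 57 genes with such a bound that were detected with miR-147 and called Absent in the control, 18 were at least 2-fold higher. KRTAP3-1, a hair keratin associated protein gene, had signals of 2747 and 12.7, at least 20.6-fold higher against the control floor of 133. QTRT1 followed at 4.25-fold and OVGP1 at 3.23-fold. Of 120 genes with such a bound that were detected in the control and called Absent with miR-147, 35 were at least 2-fold lower. RAD54L, a recombination repair gene, was at least 5.44-fold lower and MYBL2, a transcription factor of dividing cells, at least 5.02-fold lower, followed by FGFRL1 and NCAPH2, both at least 3.42-fold lower on the 1 probe set in the change table, of 2 and 4 on the array. As a sign of RNA quality, the 3'/5' signal ratio was 1.899 with miR-147 and 1.499 in the control for beta-actin, and 0.908 and 0.898 for GAPDH.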

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

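The tests of scaling in all 3 patterns, the exact interval applied to the shares of probe sets and the scaling on spike-ins were chosen after the results were seen. The list medians as deposited were known before any of these tests was run.

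Some data lay outside the gene comparisons. The 18 hybridisation spike-in probe sets, which measure control RNA added before hybridisation, were all higher on the miR-147 array, with a median of 0.352. The Alu repeat control had 0.477. Among unnamed probe sets outside the change calls with signals of at least 200 on both arrays, 41 were at least 2-fold higher and 46 at least 2-fold lower.

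The first pattern is that p53 targets were higher while replication and mitosis genes were lower. Array-wide scaling, with or without a trend in brightness, moves equally bright genes alike. In every alternative, though, the p53 median lay at percentile 100 of brightness-matched lists and the other 2 at percentile 0. Setting a median or the spike-ins to 0 shifts every gene alike and cannot change a percentile, here or in the patterns below. Only the other alternatives, quantile normalization and removal of the trend among them, could have moved it. The matched lists were drawn from the change table, which mixes increase with decrease calls, and this weakens the rank as evidence. In every alternative all detected p53 targets also lay above 0, and all detected replication and mitosis genes below 0. Single misreporting probe sets predict few genes with a second probe set called the same way. Of 49 list genes with at least 2 probe sets on the array, 43 had one (87.8%, exact 95% interval 75.2 to 95.4). All of them already had a change-called probe set, and no share over the other genes of the change table was set beside this one. The share therefore describes these lists and does not set them apart from other genes. The transfected miR, which the design names, stays open and untested, as does any other difference between the pools.

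The second pattern is that ribosomal protein and oxidative phosphorylation transcripts were higher. Scaling that follows brightness predicts that equally bright genes are higher by as much. The oxidative phosphorylation median of 0.59 lay above percentile 99 of brightness-matched lists in every alternative (lowest 99.36). Those lists were drawn from the change table and mix increase with decrease calls, while subunits lifted by scaling alone would enter it only as increases. The rank therefore cannot decide whether scaling explains all of the shift. Those matched lists had a median of 0.48 themselves, and how much of the shift scaling makes up stays open. For ribosomal proteins, whose percentile was 92.28 with 20 expression bins and 99.72 with 5, and whose median of 0.56 lay 0.124 above that of the 8 spike-ins at least as bright as the dimmest of them (SD 0.082 between single probe sets, no error for a list's median), scaling cannot be told apart from a true difference. No biological explanation was tested.

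The third pattern is that interferon-stimulated genes were higher. Scaling predicts a median among those of equally bright lists, but the lowest percentile over the alternatives was 99.51. These lists were drawn from the change table too, which weakens the rank as evidence. With the spike-ins set to 0 the median was 0.60, and 15 of the 17 genes lay above 0. Of 9 genes with at least 2 probe sets on the array, 5 had a second one called the same way (55.6%), which is under the 60% set beforehand as the sign of misreporting probe sets. Its exact 95% interval of 21.2 to 86.3 spans that bound, so misreporting probe sets cannot be told apart from a true difference with so few genes. No biological explanation was tested.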

How the results depend on the processing

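The spike-in and whole-array scalings, the caution filter and the whole-array counts were chosen after seeing the data. In each alternative that gave a value, the 8 lists that stood apart kept their sign and their side of the percentile limits. Over lists and alternatives, 275 values kept both sign and side. These include the scalings that set a median or the spike-ins to 0, which shift every gene alike, so only the sign could change under them. Of the named genes' ratios under the alternatives, 1565 moved by less than the SD of 0.39 between probe sets and 27 by more. The constant shifts of the scalings on a median or the spike-ins are themselves smaller than that SD. Setting the spike-ins to 0 lowered every list median by 0.352, and setting the detected median to 0 raised it by 0.261. The exceptions among lists were as follows, and the cause was not tested. With the median of detected genes set to 0, the medians turned to 0.26 for Wnt targets, 0.21 for YAP targets and 0.017 for apoptosis regulators. The Wnt median was 0.0010 with a pseudocount of 32, the mesenchymal one -0.25 on the spike-in scale and 0.85 without shared-probe suffixes and the housekeeping one -0.060 after quantile normalization. The ribosomal protein list reached percentile 99.72 (median 0.56) with 5 expression bins, which match brightness more coarsely. Counts of genes at least 2-fold higher and lower (576 and 766 as deposited) became 1119 and 427 with the detected median at 0, 219 and 1533 on the spike-in scale, and 322 and 502 among the brighter genes. At 1.5-fold they were 1625 and 1713, at 3-fold 110 and 217. Whole-array counts (1427 and 1574) became 2963 and 835 with the detected median at 0 (78.0% higher against 47.6%), 504 and 3431 on the spike-in scale (12.8%), 10313 and 6700 with no signal filter (60.6%), and 694 and 1069 at signals of at least 200 (39.4%). No paired analysis was possible because each group has 1 array, and no array could be left out. The seed-match comparison and its alternatives were not run. Leaving out shared-probe suffixes left 2 NF-kB and 3 histone genes, too few for a percentile. Signals near the Present floors of 133 and 144 limit ratios of dim genes.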

Other observations

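The scan of gene ontology terms, the genes named from it and the values in this part were chosen after the data were seen. Of 366 terms with 10 to 300 detected genes, 57 lay under percentile 1 and 13 above percentile 99 of 2000 random lists each. Genes of the term for assembly of nucleosomes with the centromeric histone variant CENP-A were lower, and few of them belong to the fixed lists (7.14%). Of 14 detected, 12 were at least 1.5-fold lower and 0 higher, with a median of -1.55. CENPK, a subunit of the inner kinetochore, had signals of 310 with miR-147 and 1596 in the control (-2.37), and HJURP, the chaperone of CENP-A, had 350 and 1545 (-2.14). CENPN had -1.71 and MIS18A -1.22.

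The terms for lipid metabolism differed in where they lay. Of 19 detected genes of fatty acid metabolism, 11 were at least 1.5-fold higher and 3 lower, with a median of 0.69 at percentile 99.75. The carnitine acetyltransferase gene CRAT had signals of 595 and 245 (1.28), ACADVL, the first dehydrogenase of long-chain beta-oxidation, had 4141 and 2059 (1.01), and CPT2, which acts in the import of fatty acids into mitochondria, had 0.96. Lipid catabolism genes had a median of 0.71 over 18 genes (percentile 99.25). Related terms did not stand apart: fatty acid beta-oxidation lay at percentile 94.9, lipid metabolic process at 91.9, cellular lipid metabolic process at 87.3 and fatty acid biosynthesis at 54.15. Axon guidance genes, a term that holds many guidance receptors and cytoskeletal regulators, had a median of -0.54 over 72 genes (percentile 0.1), with 34 at least 1.5-fold lower and 11 higher. These terms share genes and were not corrected for the number of terms examined.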
